A study of Mus musculus with 6 samples.

How the data were processed

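RNA-seq of mouse neuroepithelial progenitor cells, labelled Tp53-/- and Atrx-, was compared between 48 h of 1 µM AGK2 and 48 h of DMSO, with 3 labelled samples per group. Per the labels' protocols, total RNA was extracted with an RNeasy Plus kit and libraries were prepared with TruSeq kits. Per the submitters' processing notes, FastQC, HTSeq 0.9.1 and DESeq2 2.11.40.7 were used and the genome build was mm9, with no role given for each. The aligner, the gene annotation and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart.

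The authors deposited a table of counts per Ensembl gene for each sample. In 5 of the 6 files all values were whole numbers and no normalization was applied to them. In the third AGK2 file 9666 values (25.4%) were not whole, and all 37991 values equalled the mean of the other AGK2 files with a tolerance of 0. That file holds no counts of its own, so it was left out of every reported test and entered only 1 alternative, which departs from the comparison of all 6 samples that had been planned. The AGK2 files have another header and gene order than the DMSO files and 371 more identifiers, none with a count above 0. All 37 mitochondrially encoded genes are listed at 0 in the AGK2 files and hold 0.997% to 1.03% of the counts in the DMSO files. They were left out of the fits and of the library sizes used there, also after the data were examined. The printed library totals, and CPM given per library total, include them. No table held columns of other samples.

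Library totals were 37481068 and 46395402 counts for AGK2 and 22501894, 19519289 and 20265702 counts for DMSO. A library of 20265702 counts gives about 20.3 counts for a gene at 1 CPM, so genes at low CPM rest on few counts. Counts of reads without molecular identifiers are not independent molecules, and SDs come from 2 and 3 libraries.

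The 37620 identifiers in all files were named from a table of mouse gene symbols, which matched 32897 (87.4%). The genome and annotation at hand (GENCODE M21, build mm10) differ from the build of the files, so no coordinates are given and the annotation was used for gene types, GC content and shared sequence only. For each gene the share of its 25-base words found in the transcripts of other genes was computed. Comparable genes were defined, after the data were examined, as protein coding, not mitochondrial, with at most 5% of these words shared and no exon overlapping another gene. GC content was known for 13699 of 14222 tested genes (96.3%).

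Genes were filtered with filterByExpr, scaled with TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3, robust estimation, group as the only term), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The common biological coefficient of variation was 0.0585. CPM in the text are after TMM scaling, except for the values per library of Atrx and Trp53 and those of mitochondrially encoded genes, which are per library total. Standard errors come from the unshrunken coefficient and the F statistic. For 42 gene lists fixed before the data were examined, 38 had at least 5 tested members and were tested with camera in limma 3.58.1 on log CPM (prior count 2, preset correlation 0.01), with adjustment over the lists. Camera passed 13 lists, 5 higher and 8 lower. With a correlation estimated per list, camera passed 0 lists after adjustment, 7 lists had an unadjusted p below 0.05, and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, passed 34. In 36 of the 41 lists with a tested member the counts adjusted over the list alone equalled those over all genes.

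Genes were named by a rule fixed at the same time as the lists. It names 12 fixed genes and, among genes past the threshold with at least 5 CPM in the higher group and values that do not overlap between groups, the 10 largest rises and the 10 largest falls. It adds the 5 smallest p in each direction among genes with at least 50 CPM, and up to 4 members with the smallest p per list. Gene models without a proper symbol and pseudogenes were counted but not named.

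The test was tested on simulated data, counts with the means, dispersions and totals of the 5 libraries and 13953 genes tested. Of 50 genes changed by each fold, 36% were recovered at 1.2-fold, 74% at 1.5-fold, 98% at 2-fold and 100% at 4-fold. Of 186 calls, 32 fell on genes that had not been changed, a larger share than the nominal threshold states. In the simulation 13753 of the 13953 genes were unchanged, unlike in the data, where most genes were called. False calls were not split by size of change. The share therefore gives no error rate for the reported calls. A list shifted by a log2 fold change of -0.5 was called by camera. Simulated genes were drawn independently of each other, so this cannot show whether the preset correlation is adequate for the data.

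Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, other scaling factors, other filters on low counts, robust estimation off, the replicate number as a block, a minimum change of 1.5-fold and the omission of each library in turn. Alternatives added after the data were examined were all 6 files, mitochondrial genes kept, comparable genes only, each library's GC trend removed, and the omission of DMSO replicates 1 and 2 together.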

Results

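Transcript abundance was measured by RNA sequencing in primary mouse neuroepithelial progenitor cells that, according to their labels, lacked Trp53 and Atrx. Atrx encodes a chromatin remodeller of heterochromatin and telomeres that is often lost in glioma. The cells were kept for 48 h with 1 µM AGK2, a small-molecule inhibitor of the NAD-dependent deacetylase Sirt2, or with the vehicle DMSO, and 3 samples were labelled for each treatment. The comparison addresses which transcripts differ between AGK2 and DMSO in progenitors labelled as lacking Atrx, in a study concerned with senescence. All 37991 of the 37991 values of the third AGK2 sample equalled the mean of the other AGK2 samples exactly (tolerance 0), so this sample was not counted as a replicate, and 2 AGK2 libraries were compared with 3 DMSO libraries. Total counts were 37481068 and 46395402 in the AGK2 libraries and 22501894, 19519289 and 20265702 in the DMSO libraries.

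The values of the 2 treatments had been produced differently. The AGK2 files listed 371 gene identifiers that the DMSO files lacked, and gave all 37 mitochondrially encoded genes as 0 although these took a mean of 1.01% of the DMSO counts. Processed pseudogenes, the intronless copies of expressed genes, were mostly higher in the AGK2 libraries, whether through counting or treatment. Every AGK2 file was made one way and every DMSO file another, so treatment is confounded with file production, and each difference below is one between the libraries labelled AGK2 and DMSO. Counts were therefore also given, for all genes and for some lists, over 6597 comparable genes. These are protein coding, share at most 5% of their sequence with other genes and overlap no exon of another gene. Many genes named below are not comparable, also where this is not stated. The labels do not state that samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

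Most tested genes of the immediate early response and of hypoxia and glycolysis were higher in the AGK2 libraries, and most of the cell cycle, DNA repair and cholesterol synthesis were lower. Each of these lists passed camera at the preset correlation and had adjusted p = 0.125 with an estimated correlation. Egr1, an immediate early transcription factor, stood at 515 ± 23.2 CPM (SD, n = 2) with AGK2 and 19.8 ± 0.406 CPM (SD, n = 3) with DMSO. Vegfa, the angiogenic growth factor induced by hypoxia, stood at 530 ± 2.67 against 77.9 ± 2.76 CPM. Lmnb1, which encodes the nuclear lamina protein lamin B1, fell from 678 ± 18.7 to 238 ± 1.31 CPM, and the proliferation marker Mki67 from 662 ± 9.28 to 309 ± 9.68 CPM. Of 14222 genes tested with edgeR, 4809 were higher and 4435 lower with AGK2, of which 1366 and 1142 differed by at least 2-fold. Pseudogenes made up 509 of the 1366 rises and 54 of the 1142 falls of at least 2-fold. Among the comparable genes 2155 were higher and 2070 lower, of which 380 and 430 differed by at least 2-fold. In 10796 genes the AGK2 and DMSO values did not overlap, where chance alone gives 20% of genes.

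**Figure D1:**
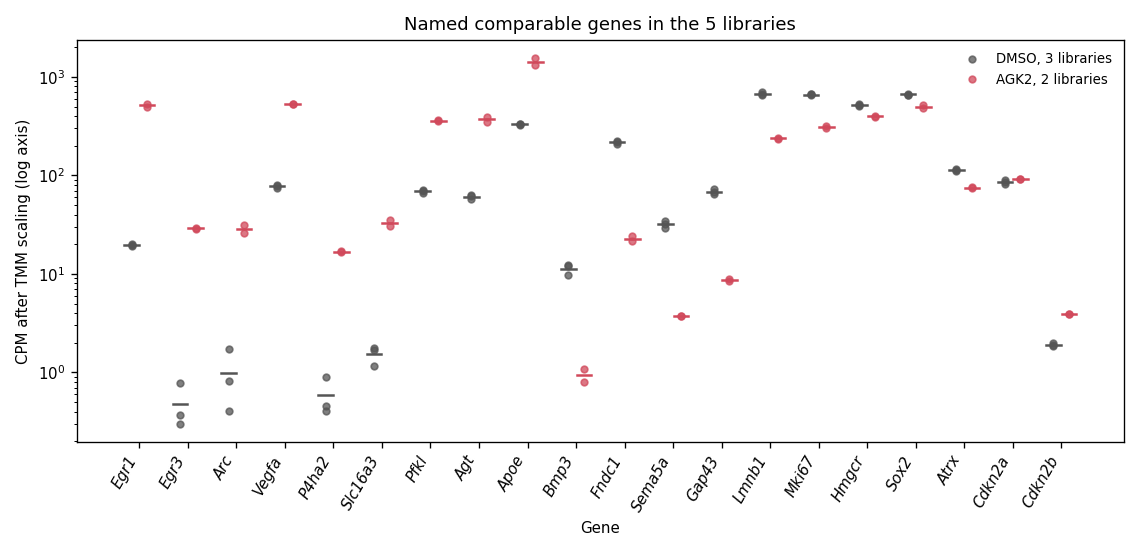
Expression of 20 named comparable genes in the 5 libraries, in CPM (counts scaled to library size by TMM) on a log axis, with a point per library and a line at each group mean for DMSO (3 libraries, grey) and AGK2 (2 libraries, red). Egr1 lay near 515 CPM in the AGK2 libraries and 19.8 CPM in the DMSO libraries, while Cdkn2a lay at 92.5 and 85.9 CPM.

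Transcripts of the genotyped and targeted genes were present in every library. Atrx (ENSMUSG00000031229) had 74.6 and 78.2 CPM in the AGK2 libraries and 108, 111 and 114 CPM in the DMSO libraries, a log2 fold change of -0.59 ± 0.057 (SE, edgeR adjusted p = 4.4e-08) that became -0.26 after each library's trend with GC content was removed. Trp53 (ENSMUSG00000059552), which encodes the tumour suppressor p53, had 55.1 and 52.1 CPM with AGK2 and 43.5, 45.9 and 45.4 CPM with DMSO, with an edgeR adjusted p of 0.0137 that 3 of 18 alternatives ended (range 0.000344 to 0.231). Counts summed over a whole gene also hold exons outside a deleted part, so these levels check neither deletion. Sirt2 (ENSMUSG00000015149), the target of AGK2, stood at 168 ± 6.74 CPM with AGK2 and 154 ± 6.96 CPM with DMSO. Its edgeR adjusted p of 0.0448 passed the threshold by little, and 9 of 18 alternatives ended the call, with adjusted p from 4.07e-05 to 0.731 over all of them. The related deacetylase Sirt1 was lower with AGK2 (22.4 ± 4.56 against 37.1 ± 2.57 CPM, edgeR adjusted p = 7.17e-05). Sirt1 and Sirt2 each overlap an exon of another gene, so neither is comparable. Among 18 sirtuins and histone deacetylases 6 were higher and 7 lower, with a camera adjusted p of 0.605. Hdac1 was 1.78-fold and Sirt6 1.37-fold lower, while Hdac7 was 1.60-fold higher, and Hdac1 shares 41.8% of its 25-base words with other genes.

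Of 27 immediate early genes, which are induced within minutes of growth factor or stress signals, 25 were higher and 1 was lower with AGK2, with a median log2 fold change of 1.73; the counts adjusted over the list alone were 25 and 1. The list passed camera with an adjusted p of 1.12e-08 at the preset correlation, and had adjusted p = 0.125 with an estimated correlation. Egr3 was 58.4-fold, Egr2 26.7-fold and Egr1 26.1-fold higher, and Arc rose from 0.982 ± 0.677 to 28.7 ± 3.41 CPM. With DMSO Egr3 stood at 0.48 ± 0.255 and Egr2 at 0.999 ± 0.11 CPM, so their folds rest on few DMSO counts. Jun, a component of the AP-1 transcription factor, was 4.01-fold higher and Dusp6, a phosphatase of ERK, 4.28-fold higher. Jun overlaps an exon of another gene. The 1 lower member was Btg2, an antiproliferative gene, at 178 ± 3.77 against 284 ± 5.02 CPM. Among 21 comparable members 19 were higher and 1 was lower, with a median of 1.81. Of 16 output genes of the MAPK pathway, which includes Dusp6, 10 were higher and 4 lower with a camera adjusted p of 0.106. Spry4 and Spry1, feedback inhibitors of growth factor signalling, were 2.93-fold and 2.12-fold higher, and cyclin D1 (Ccnd1) 2.04-fold higher.

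Of 39 genes of glycolysis and the hypoxia response, 34 were higher and 2 lower with AGK2 (34 and 2 adjusted over the list alone), with a median log2 fold change of 0.89. The camera adjusted p was 5.25e-08 at the preset correlation, and adjusted p = 0.125 with an estimated correlation. The liver-type phosphofructokinase Pfkl rose from 69.3 ± 2.42 to 359 ± 3.32 CPM, and Pdk1, the kinase that restrains pyruvate dehydrogenase, from 24.8 ± 0.19 to 180 ± 21.0 CPM. P4ha2, a collagen prolyl hydroxylase, was 28.9-fold higher, Slc16a3, a lactate exporter, 21.4-fold higher and Egln3, an oxygen-sensing hydroxylase, 9.98-fold higher. With DMSO P4ha2 stood at 0.584 ± 0.266 and Slc16a3 at 1.53 ± 0.329 CPM, so the folds of both rest on few DMSO counts. Gapdh, itself a member of the list, stood at 105 ± 2.71 CPM with AGK2 against 1080 ± 14.4 CPM with DMSO. Gapdh shares 28.0% of its 25-base words with other genes, and its reads could be split with its pseudogenes. Among 20 comparable members 18 were higher and 1 lower, with a median of 1.40.

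All 52 genes of G2 and M phase were lower with AGK2 (52 also adjusted over the list alone), with a median log2 fold change of -1.20. Of 46 S phase genes 40 were lower and 4 higher, with a median of -0.60 and the same counts adjusted over the list alone. The camera adjusted p was 3.61e-20 for G2 and M phase and 3.89e-09 for S phase at the preset correlation, and each list had adjusted p = 0.125 with an estimated correlation. The spindle assembly factor Tpx2 fell from 372 ± 4.21 to 136 ± 0.654 CPM, and Tacc3, a centrosome protein, from 262 ± 3.65 to 95.7 ± 0.638 CPM. Cdc20, an activator of the anaphase-promoting complex, was 2.77-fold lower and the chromatin protein Hmgb2 4.30-fold lower. In S phase, the ribonucleotide reductase subunits Rrm2 and Rrm1 were 2.39-fold and 1.99-fold lower, and Uhrf1, a cofactor of maintenance DNA methylation, was 2.19-fold lower. None of these named genes is comparable. Uhrf1, Cdc20, Hmgb2 and Rrm2 share 28.2%, 33.4%, 23.4% and 15.5% of their 25-base words with other genes. Rrm1 and Tpx2 share 6.52% and 6.27%, and Tacc3 overlaps an exon of another gene. All 25 comparable G2 and M phase genes were lower, with a median of -1.13, as were 19 of 22 comparable S phase genes, with a median of -0.53. Replication-dependent histone genes had 1 higher and 16 lower of 25 (camera adjusted p = 0.00398, adjusted p = 0.554 with an estimated correlation). Only 2 of these 25 were comparable, and Hist1h4i, at 2.66 ± 0.359 against 9.78 ± 0.578 CPM, shares 38.3% of its 25-base words with other genes. The other lower histone genes with the smallest p lay below Hist1h4i in each group. The 1 higher histone gene, Hist1h1c, named outside the rule, stood at 167 ± 4.07 against 140 ± 3.36 CPM.

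**Figure D2:**
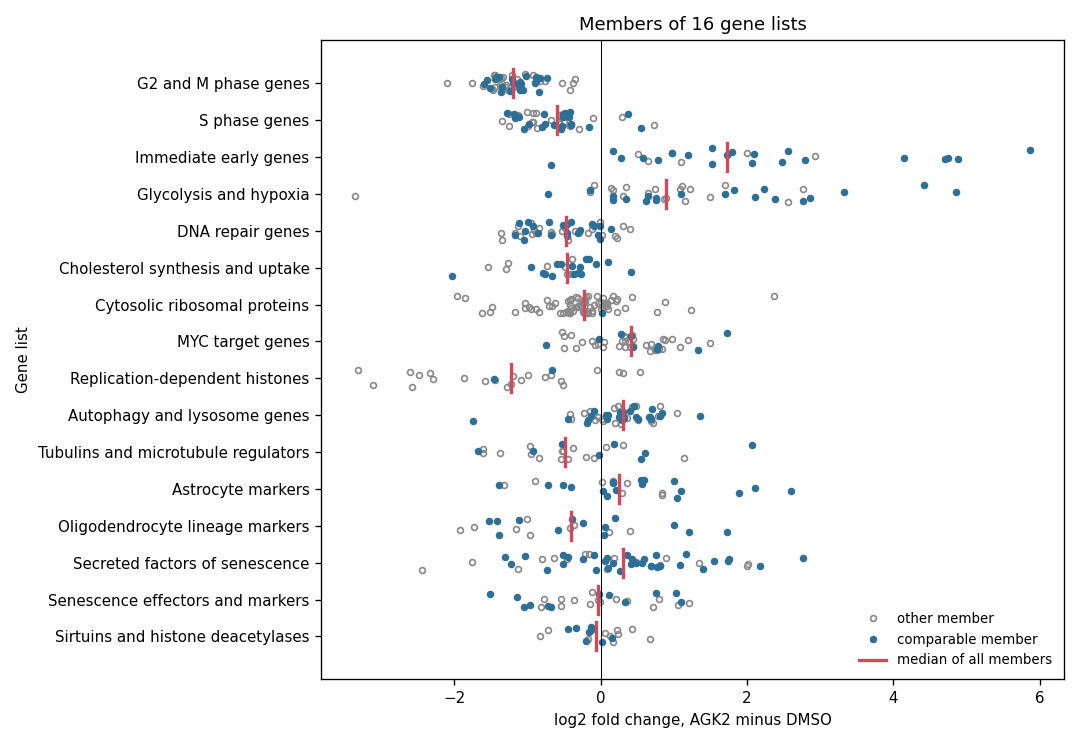
Log2 fold change (AGK2 minus DMSO) of the members of 16 gene lists, with filled points for comparable members, open points for other members and a red bar at the median of all members. G2 and M phase genes lay left of 0 with a median of -1.20, and immediate early genes reached from -0.68 to 5.87 with a median of 1.73.

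Of 48 DNA repair genes 34 were lower and 4 higher with AGK2 (34 and 4 adjusted over the list alone). The camera adjusted p was 8.86e-07, with adjusted p = 0.125 with an estimated correlation. Fanci, of the Fanconi anaemia pathway, was 2.57-fold lower, the helicase Blm 2.17-fold, the DNA ligase Lig1 1.92-fold and H2afx, which encodes the histone variant phosphorylated at DNA breaks, 1.87-fold lower. Of 25 genes of cholesterol synthesis and uptake 22 were lower and 1 higher (22 and 1 adjusted over the list alone), with a median log2 fold change of -0.46. Its camera adjusted p was 6.75e-06, with adjusted p = 0.125 with an estimated correlation. Hmgcr, the rate-limiting enzyme of the pathway, fell from 520 ± 7.14 to 398 ± 6.57 CPM, and the sterol carrier Stard4 from 295 ± 9.95 to 153 ± 13.5 CPM. Acat2 and Fdps were 2.91-fold and 2.42-fold lower, but share 45.5% and 28.4% of their 25-base words with other genes. Fatty acid synthesis genes moved both ways, 7 of 19 higher and 7 lower (camera adjusted p = 0.973), with Acly 1.51-fold lower and Fads2 1.41-fold higher.

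Of 44 targets of the transcription factor MYC 31 were higher and 8 lower (31 and 8 adjusted over the list alone; camera adjusted p = 0.000719, adjusted p = 0.125 with an estimated correlation). Myc itself rose from 57.4 ± 2.93 to 190 ± 14.5 CPM, and Ppan, a ribosome biogenesis factor, from 22.7 ± 1.10 to 51.9 ± 2.88 CPM. Ppan shares 6.91% of its 25-base words with other genes. Only 9 MYC targets were comparable, 7 higher and 1 lower, with a camera adjusted p of 0.0422 at the preset correlation. With an estimated correlation their camera adjusted p was 0.519. Cytosolic ribosomal protein genes had 11 higher and 52 lower of 77, or 12 and 52 adjusted over the list alone. Their camera adjusted p was 5.72e-05, with adjusted p = 0.509 with an estimated correlation, and only 1 of the 77 was comparable. Of 48 autophagy and lysosome genes 29 were higher and 8 lower (29 and 8 adjusted over the list alone), with a median log2 fold change of 0.30. Its camera adjusted p was 0.00508, with adjusted p = 0.403 with an estimated correlation. The lysosomal enzymes Hexa, Ctsl and Gns were 1.75-fold, 1.72-fold and 1.60-fold higher. Nuclear genes of oxidative phosphorylation had 16 higher and 31 lower of 75 (camera adjusted p = 0.219), including Cox7c at 151 ± 7.20 against 335 ± 7.18 CPM, a gene that shares 25.3% of its 25-base words with others.

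Markers and effectors of senescence did not pass camera as a group. The list mixes genes that rise in senescence, such as Cdkn1a, with genes that fall, such as Lmnb1. Camera asks for a shift in a common direction, so its result for this list cannot speak for or against senescence. Of 27 tested, 10 were higher and 11 lower with AGK2, the same counts adjusted over the list alone. The median log2 fold change was -0.03 with a camera adjusted p of 0.562. Its 12 comparable members had 4 higher and 6 lower, with a median of -0.34 and a camera adjusted p of 0.482. With each library's GC trend removed the list median was -0.13. Over camera alternatives at the preset correlation adjusted p ranged from 0.394 to 0.628, against 0.000681 with fry, which does not compare the list with other genes. The cyclin-dependent kinase inhibitors differed in direction. Cdkn2b (p15) rose from 1.92 ± 0.0626 to 3.93 ± 0.00891 CPM (edgeR adjusted p = 0.000264) and Cdkn1a (p21) from 3.29 ± 0.247 to 6.79 ± 0.783 CPM (edgeR adjusted p = 1.78e-05), both at low levels, and Cdkn1a overlaps an exon of another gene. Cdkn1b (p27) fell from 346 ± 1.04 to 157 ± 9.29 CPM. Cdkn2a, which encodes p16 and p19Arf, stood at 92.5 ± 0.305 against 85.9 ± 3.35 CPM with an edgeR adjusted p of 0.113. It was called higher in 4 of 19 alternatives and lower in 1, with each library's GC trend removed (log2 fold change -0.13, adjusted p = 0.024). Adjusted p ranged from 0.0196, for a higher level, to 0.403 over all of them. Lmnb1 was 2.85-fold lower (edgeR adjusted p = 3.73e-15), Gas1, a growth arrest gene, 2.31-fold higher and the adhesion receptor Cd44 2.13-fold higher. Gas1 overlaps an exon of another gene. Of 50 genes for factors secreted by senescent cells, 25 were higher and 12 lower (25 and 12 adjusted over the list alone), with a median of 0.31 and a camera adjusted p of 0.142. The median was 0.42 among 33 comparable members and 0.14 with each library's GC trend removed. The list includes Vegfa, Jun and Igfbp5, which was 1.70-fold higher. It also includes Hmgb1, which stood at 132 ± 4.63 against 718 ± 10.7 CPM and shares 24.3% of its 25-base words with other genes. p53 target genes had 20 higher and 9 lower of 41 (camera adjusted p = 0.233). Gadd45a was 3.23-fold and Abhd4 1.72-fold higher, and Ephx1, an epoxide hydrolase, was 1.78-fold higher. Gadd45a and Ephx1 overlap exons of other genes.

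Cell identity markers were also compared. Of 26 astrocyte markers 16 were higher and 6 lower (16 and 6 adjusted over the list alone; camera adjusted p = 0.0343, adjusted p = 0.403 with an estimated correlation). Angiotensinogen (Agt) rose from 61.1 ± 2.62 to 371 ± 29.8 CPM, apolipoprotein E (Apoe) from 331 ± 4.51 to 1430 ± 156 CPM and the glutamate transporter Slc1a3 from 676 ± 5.80 to 1350 ± 29.1 CPM. The lower member with the smallest p, Aldh1l1, named outside the rule, stood at 28.6 ± 2.26 against 71.6 ± 2.91 CPM and is not comparable. Gfap was near its detection limit at 0.539 ± 0.285 against 0.447 ± 0.294 CPM. In 5 of 16 alternatives the list's call ended, such as without DMSO replicate 3 (camera adjusted p = 0.078). Camera at the preset correlation gave adjusted p from 0.0322 to 0.145, and fry gave 0.000421. Of 22 oligodendrocyte lineage markers 13 were lower and 5 higher (13 and 5 adjusted over the list alone; camera adjusted p = 0.0343, adjusted p = 0.403 with an estimated correlation). Among 13 comparable members 5 were lower and 4 higher. The higher member with the smallest p, Sox10, named outside the rule, stood at 9.33 ± 0.115 against 2.81 ± 0.772 CPM and is comparable. The receptors Pdgfra and Gpr17 were 3.80-fold and 3.32-fold lower, and neither is a comparable gene. This call ended with the replicate number as a block (adjusted p = 0.0535), without AGK2 replicate 2 (0.0971) and among comparable genes (0.482). Over camera alternatives at the preset correlation adjusted p ranged from 0.0048 to 0.482, against 0.000506 with fry. Neural stem and progenitor markers had 10 higher and 10 lower of 27 (camera adjusted p = 0.634), with a median log2 fold change of -0.02 and a mean of 0.01, while camera gave the direction as down. Fabp7, a radial glia lipid carrier, fell from 1420 ± 22.9 to 605 ± 18.6 CPM, the proneural factor Ascl1 from 185 ± 3.72 to 95 ± 0.476 CPM and Sox2 from 665 ± 8.01 to 501 ± 19.3 CPM. Slc1a3, also on this list, rose as given above. Of 22 neuron markers 5 were higher and 9 lower (camera adjusted p = 0.16), with the growth cone gene Gap43 7.94-fold and Syt1 3.21-fold lower.

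The largest rises among the named genes outside the lists above were those of Snrpf, Bloc1s1, Tpm3-rs7 and Ddt, at 94.0-fold, 63.2-fold, 22.6-fold and 19.5-fold. With DMSO they stood at only 0.102, 0.152, 0.98 and 0.628 CPM. These 4 genes share between 23.7% and 82.5% of their 25-base words with other genes, so their levels are uncertain. The same holds for the falls of Hnrnpa3 (15.6-fold, 28.3% shared), Duxbl1 (7.80-fold, 97% shared) and Tsnax (22.6-fold, 14.9% shared). Among genes with little shared sequence, the bone morphogenetic protein Bmp3 fell from 11.3 ± 1.36 to 0.943 ± 0.199 CPM, Fndc1, which encodes a fibronectin-domain protein, from 217 ± 5.40 to 22.9 ± 1.68 CPM, and the semaphorin Sema5a from 31.9 ± 2.57 to 3.74 ± 0.0124 CPM. Sema3d and the contactin gene Cntn6 were 7.60-fold and 7.75-fold lower. Cyclin D2 (Ccnd2), which overlaps an exon of another gene, rose from 50.9 ± 3.21 to 380 ± 2.40 CPM. When the same rule was applied to comparable genes, a step added after the data were examined, it also named Rasl11a (13-fold higher), Synpo (10.5-fold) and Klf10 (7.57-fold) and the lower genes Ecm2, Vgll3, Tmem100 and Rlbp1 (6.49-fold, 6.42-fold, 5.95-fold and 5.21-fold).

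**Figure D3:**
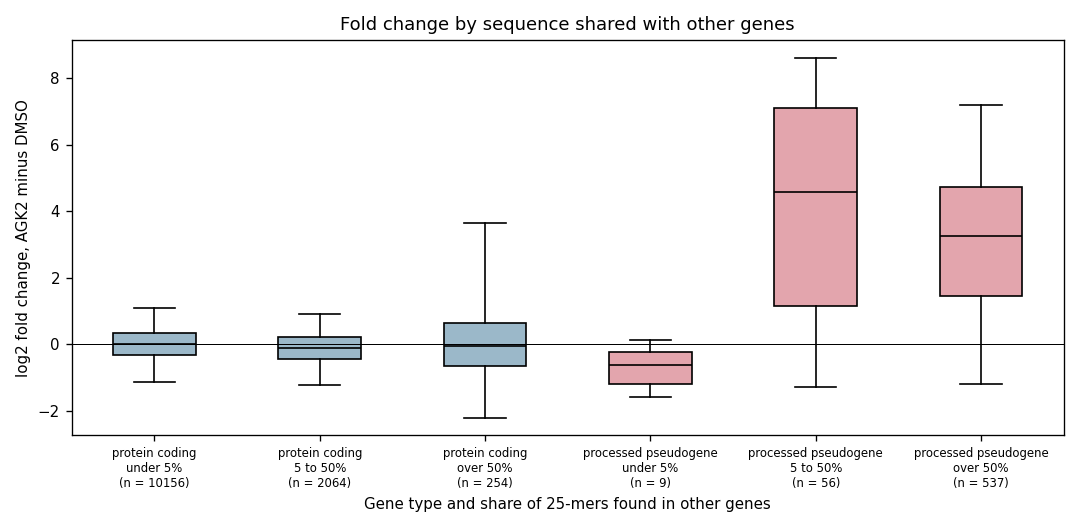
Log2 fold change (AGK2 minus DMSO) of tested protein-coding genes and processed pseudogenes by the share of their 25-base words found in other genes, with boxes from the lower to the upper quartile, a line at the median and whiskers to the 5th and 95th percentiles. The 537 processed pseudogenes with over 50% shared had a median of 3.26 and the 9 with under 5% a median of -0.62, against 0.02 for 10156 protein-coding genes with under 5% shared.

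Chromatin lists outside the histones had smaller median log2 fold changes, though not every member differed less. The medians were -0.18 for Polycomb and heterochromatin genes, -0.07 for histone acetyltransferases and partners and -0.22 for imprinted genes, against -1.22 for the histones. Of 39 genes of the Polycomb and heterochromatin machinery 8 were higher and 18 lower with AGK2 (camera adjusted p = 0.0543), a list that passed camera without a filter on low counts (adjusted p = 0.0253) and without AGK2 replicate 1 (0.0494). Over camera alternatives at the preset correlation adjusted p ranged from 0.0253 to 0.174, against 0.341 with an estimated correlation and 0.000681 with fry, which does not compare a list with other genes. Its lower members include the methyltransferases Ezh2 and Dnmt1 at 1.76-fold and 1.52-fold lower. Of 23 histone acetyltransferases and partners of the histone H4 lysine acetylation machinery 4 were higher and 9 lower (camera adjusted p = 0.476), with Ogt 1.64-fold lower and Wdr5 1.36-fold higher. Imprinted genes had 6 higher and 12 lower of 26 (camera adjusted p = 0.16), and Mest was 1.97-fold lower. The only tested pluripotency and germline gene, Ddx4, stood at 2.03 ± 0.557 against 1.40 ± 0.339 CPM. Of 24 tubulins and microtubule regulators, some of them substrates or partners of Sirt2, 15 were lower and 6 higher (15 and 6 adjusted over the list alone; camera adjusted p = 0.0144, adjusted p = 0.509 with an estimated correlation). The lower members include Tuba1b, Tuba1a and Stmn1, which share 70.1%, 78.4% and 23.4% of their 25-base words with other genes. Among 8 comparable members 4 were higher and 3 lower, with a camera adjusted p of 0.96, and over camera alternatives at the preset correlation adjusted p ranged from 0.0048 to 0.96, against 0.000681 with fry.

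The remaining lists did not pass camera. For lists given here without counts adjusted over the list alone, those equalled the counts over all genes, except for 25 higher of ATF4 and unfolded protein response genes, 13 higher of matrix genes, 4 higher of endothelial markers and 7 lower of BMP and TGF-beta targets, each adjusted over the list alone. Stress lists had 24 higher and 11 lower of 46 for ATF4 and the unfolded protein response (adjusted p = 0.15), 10 and 7 of 23 for NRF2 targets (0.416), 10 and 5 of 20 for heat shock genes (0.34) and 10 and 6 of 22 for FoxO targets (0.562). The ATF4 list member Vldlr was 3.08-fold, the NRF2 target Abcc1 2.73-fold, the heat shock gene Hsph1 1.67-fold and the FoxO target Txnip 3.44-fold higher, of which Txnip is not a comparable gene. Among 11 comparable FoxO targets 2 were higher and 6 lower, with a median of -0.18 (camera adjusted p = 0.137). Interferon-stimulated genes had 19 higher and 7 lower of 48 (camera adjusted p = 0.261), with Ifit2 3.06-fold lower and Tor3a 1.92-fold higher, and NF-kB targets 8 and 3 of 19 (0.294), with Ier3 5.55-fold higher and Vcam1 2.60-fold lower. Signalling lists had 8 higher and 5 lower of 18 for Notch (camera adjusted p = 0.562), 5 and 2 of 14 for Wnt (0.416) and 5 and 5 of 14 for BMP and TGF-beta targets (0.974). The Notch ligand Dll3 was 2.90-fold lower and Id1, a BMP target, 1.71-fold higher. Extracellular matrix and mesenchymal genes had 12 higher and 10 lower of 29 (camera adjusted p = 0.497), with Loxl2, which shares 46.8% of its 25-base words with other genes, 5.43-fold higher and Lgals1 2.76-fold lower. Of 7 genes of the aryl hydrocarbon receptor and xenobiotic response 3 were higher (camera adjusted p = 0.4).

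Few markers of other cell types were tested. Endothelial and pericyte markers had 3 higher and 1 lower of 5 (camera adjusted p = 0.476), with Cspg4, also a marker of oligodendrocyte progenitors, at 232 ± 29.6 against 202 ± 3.49 CPM, and fibroblast and meningeal markers 1 higher and 5 lower of 8 (0.294), where Pdgfra, shared with the oligodendrocyte lineage list, was the most abundant of the 4 named members at 37.2 ± 0.608 against 141 ± 5.66 CPM. Only 4 microglia and macrophage markers were tested, of which Hexb was higher and Tmem119 was lower at under 1 CPM in both groups, a call that DESeq2 and limma-voom did not make. Of 3 epithelial and ependymal markers Foxj1 was lower, at 10.1 ± 0.629 against 15.8 ± 1.28 CPM, and Otx2 stood at 29.7 ± 1.65 against 33.4 ± 1.05 CPM.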

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

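The tests on comparable genes, pseudogenes and GC content were all added after the data were examined, and those on comparable genes also after their results had been seen.

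Values outside the comparison drew attention in both groups. The third AGK2 file carried no measurement of its own, since 100% of its values were means of the other AGK2 files. Mitochondrially encoded genes took a mean of 1.01% of the DMSO counts and were 0 throughout the AGK2 files, with mt-Co1 at 4290 ± 34.0 CPM (SD, n = 3), mt-Cytb at 1880 ± 61.6 CPM and mt-Nd1 at 1470 ± 18.9 CPM in the DMSO libraries.

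Processed pseudogenes were higher in the AGK2 libraries, 487 of 602 of them past the edgeR threshold and 55 lower. A candidate explanation is that reads shared between genes and their copies were counted differently in the files of the groups. The median log2 fold change was 3.26 for 537 of the 602 with over 50% of their sequence shared and -0.62 for only 9 with under 5%, a difference of 3.88, where equal medians would have argued against it. The 56 with shares in between had a median of 4.59, so the rise came with shared sequence but did not grow steadily with it. No biological explanation was tested, and a treatment effect on pseudogenes with shared sequence alone stays open.

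Immediate early and hypoxia genes were higher in the AGK2 libraries. Shared reads as the whole cause are argued against by the comparable genes, where the lower of the list medians was 1.40 and both lists passed camera at the preset correlation, with adjusted p = 0.295 with an estimated correlation, and GC content by the values with each library's GC trend removed, where it was 0.91. An effect of AGK2 and a separate culture, harvest or sequencing of the groups both stay open, since the labels name no batch and no test of it was possible. Other differences in how the files of the groups were made also stay open. Culture density, oxygen and the time since the last medium change may all move these lists, and no value here measures them.

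Cell cycle genes were lower in the AGK2 libraries. The list median closer to 0 was -0.53 among comparable genes and -0.54 with the GC trend removed, both past the camera threshold at the preset correlation. Among comparable genes S phase had adjusted p = 0.295 with an estimated correlation and G2 and M phase 0.425. The medians argue against shared reads and GC content as the whole cause. Slower proliferation under AGK2 may underlie the difference, as may a denser or older culture. Other differences in how the files of the groups were made may also do so. None of these was tested, and all stay open.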

How the results depend on the processing

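The use of all 6 files, of comparable genes, of GC offsets, of mitochondrial genes and the omission of DMSO replicates 1 and 2 together were chosen after the data were examined. Against 4809 genes higher and 4435 lower, the counts with edgeR, DESeq2 or limma-voom stayed within 1.5 times the reported ones except in these cases. Comparable genes alone gave 2185 and 2046, from fewer genes tested. A minimum change of 1.5-fold left 2324 and 2139. Without DMSO replicates 1 and 2, 3271 were higher and 2615 lower, where the lone DMSO library was assumed to vary like the AGK2 pair, so these counts say little. Leaving out each library in turn gave 4485 to 5160 higher and 3776 to 4677 lower, where a lone AGK2 library was assumed to vary like the DMSO libraries. With all 6 files 5485 and 4914 were called. Calls shared with the reported ones had the same direction in every other fit except that with GC offsets, where 8161 of 8203 did.

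No pairing by replicate number was seen for replicates 1 and 2, whose differences correlated at -0.008 across genes between the AGK2 and DMSO groups. Replicate 3 could not be checked in this way, so a pairing of the samples stays open. With the replicate number as a block 4397 genes were higher, 4084 lower and 11 lists passed. The block ended the calls of Sirt2, Eng, the astrocyte list and the oligodendrocyte list.

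Against 13 lists, camera with an estimated correlation passed 0 and fry 34, and leaving out each library passed 12 to 14. Over the camera alternatives at the preset correlation, adjusted p was at most 1.20e-11 for G2 and M phase, 1.47e-05 for S phase, 5.94e-07 for immediate early genes and 3.40e-06 for glycolysis and hypoxia. The tubulin list changed direction among comparable genes (adjusted p = 0.96), as did BMP and TGF-beta targets with fry (0.0247). With the GC trend removed, the log2 fold changes of Cdkn2a and Cspg4 became -0.13 and -0.022. The cause was not tested. Of the other values of named genes 31 lost and 12 gained a call, and of list values 21 and 22. Scaling moved the median of all genes by at most 0.038, and the share of higher calls lay between 51.3% and 56.2%. The pseudocounts and filters planned for normalized values were not run, since the files hold counts, nor was leaving out the averaged file, which is the fit as reported.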

Other observations

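No test in this part offers an explanation.

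Skeletal muscle transcripts were present in part of the DMSO group. Of 20 skeletal muscle markers, a list written after the first of them had been seen, 17 were higher in DMSO replicates 1 and 2 than in each of the other 3 libraries. Myh4, a fast myosin heavy chain, had 145 and 108 counts in DMSO replicates 1 and 2 and 0 in the other libraries. Ckm, the muscle creatine kinase, had 43 and 27 counts there and Pvalb 35 and 23, with 0 in the other libraries, and Acta1 had 97 and 100 counts against 3 to 6. Eno3, Casq1 and Tnnc2 did not follow.

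Mitochondrially encoded genes were uneven in the DMSO libraries. Against 4290 CPM for mt-Co1, the neighbouring respiratory genes mt-Co2, mt-Co3 and mt-Atp6 stood at 10.3 ± 1.30, 11.1 ± 0.819 and 11.8 ± 0.478 CPM (SD, n = 3).

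The libraries of a group lay close to each other. The correlation of log CPM was 0.9935 for the AGK2 pair, 0.9918 to 0.9932 for the DMSO pairs and 0.9248 to 0.9315 between groups. A chi-square statistic of counts over genes was 2.25 to 2.72 per degree of freedom for the DMSO pairs. It was 15.9 for the AGK2 pair and 127 to 146 between groups. The statistic grows with depth, and library totals were 37481068 and 46395402 counts for AGK2 against 19519289 to 22501894 for DMSO. At an equal spread between libraries the statistic grows at most in proportion to depth. The largest AGK2 total, 46395402, and the smallest DMSO total, 19519289, differ by a far smaller factor than 15.9 and 2.72 do. These values argue against depth alone for the AGK2 pair. A larger spread between the AGK2 libraries than between the DMSO libraries rests on this pair alone, and its cause was not tested. The first principal component of log CPM took 88.4% of the variance and parted the groups, and the second took 4.66%.

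The fold change also followed GC content. In comparable genes its median rose from -0.21 in the lowest quartile of GC content to -0.03, 0.10 and 0.19 in the next quartiles. Long non-coding and antisense genes were lower with AGK2 on the median, at -0.47 for 95 lincRNA genes and -0.57 for 191 antisense genes.

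Comparable genes were also grouped by the letters that open their symbols, giving 67 families of at least 10 genes. With camera 0 families passed adjustment, 9 had an unadjusted p below 0.05, and 0 passed with an estimated correlation. The smallest adjusted p was 0.14, for 11 Cdc genes of which 8 were lower and 1 higher.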
